A study of Homo sapiens with 2 samples.

How the data were processed

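Gene expression was measured on 2 two-colour Agilent arrays printed with 60-mer probes, each hybridised with RNA from HCT116 cells carrying a FLANC expression vector and RNA from HCT116 cells carrying the empty vector. The spot intensity values, the mean pixel brightness of a spot and the median of its local background in each channel, were read from the scanner images with Feature Extraction 11.0.1.1, per the file headers, while the submitters' processing notes name Agilent Feature Extraction 8.5.1.1. The processed signals in the same files were background-subtracted with spatial and multiplicative detrending and then dye-normalised by a linear and a lowess step, per the file headers. The deposited log10 ratio of Cy5 over Cy3 was computed by Feature Extraction from those processed signals, and the authors' series table held the same log10 values at every position within 1e-07 on both arrays. That table was therefore on the log10 scale, with a median of 0 on each array, and its columns were not turned to a common direction. The p-value that Feature Extraction gave each spot, deposited in the same files, comes from an error model within 1 array and was not used in any test. Both arrays lay on 1 slide, per the file headers, so no slide effect could be estimated.

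The labels put empty vector RNA in Cy3 and FLANC vector RNA in Cy5 on the array of replicate 1. On the array of replicate 2 the channel order is reversed, with the FLANC vector first, but both channels carry the dye label Cy5. Channel 1 is Cy3 on replicate 1, and the description of replicate 2 names the samples in the opposite order. The array of replicate 2 was therefore likely a dye swap, and its log2 ratio was multiplied by -1. This orientation is likely and not settled by the labels. Counts of calls and the values that change sign with the array of replicate 2 turned the other way are given as an alternative.

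Intensities were corrected with limma's normexp method (offset 50) on mean signal and median background, and normalised within each array by loess, with control spots and spots flagged as non-uniform or as population outliers at weight 0. Controls were then removed, flagged spots (415 on replicate 1 and 417 on replicate 2) were left out, and the spots of 1 probe were averaged. The remaining spots held 34127 distinct probes, of which 999 were printed 10 times. A probe was kept if it was well above background in at least 1 channel on each of both arrays, which left 16989 probes. The probe with the highest mean intensity stood for a gene, giving 13845 genes or unnamed transcripts, 12156 of them with a gene name. Gene names were updated through RefSeq accessions of GRCh38.p14, which matched 24827 probes, and the names in the files were kept otherwise. Probe positions are those of the files, on hg18. No genome was used here, so exons and untranslated regions are not annotated.

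Log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg at 0.05, 1 residual degree of freedom and 8.34 prior degrees of freedom). Errors are SDs over the 2 arrays, n = 2, unless an SE is named. The labels call the arrays biological replicates but do not say that the cells were cultured separately, so p-values measure the spread between these arrays, pooled over genes. With 8.34 prior against 1 residual degree of freedom, the variance used for a gene came mostly from a prior shared by all genes. The number of arrays limits the precision. The SD of the log2 ratio over the 10 spots of a probe had a median of 0.036 on replicate 1 and 0.052 on replicate 2. On data simulated for this comparison over 13845 genes, 100% of 50 genes changed by a log2 ratio of 1 were recovered, 32% of 50 genes changed by 0.5, and 12 unchanged genes were called. A list shifted by 0.6 was found in a separate simulation, with 0 other lists called. In both simulations genes varied independently, so false calls of lists with correlated members were not tested. The correlation estimated for a list rests on 1 residual degree of freedom. It reflects only how far members differed between the 2 arrays in the same direction. For the lists called below it ran from -0.077 for fatty acid synthesis to 0.638 for histone genes and 1 for ribosomal proteins. These values do not measure how strongly the members are correlated.

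Before the data were examined, 34 gene lists, the rule for naming genes, the tests and the alternatives were fixed. The rule named STAT3 and VEGFA, the 12 called genes with the largest rise and the 12 with the largest fall that moved the same way on both arrays, and up to 4 called members of each list by size, or 2 members where none was called. The largest rises and falls were chosen only among transcripts with a gene name. Lists were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. With an estimated correlation camera's test rests on the 1 residual degree of freedom, so almost no list could pass. Its smallest adjusted p over all lists was 0.932, and no conclusion is drawn from it for any list. The lists had 2 to 62 members tested, and camera was run on the 33 lists with at least 3. The alternatives covered the orientation of replicate 2, each array alone, background correction, Agilent's processed signals, the authors' log ratios, normalization, the filter on dim probes, outlier flags, the choice of probe and the variance model. The 3 settings with trends removed were added after seeing the data, in which a lowess trend (span 0.3) with the probe's start position in its transcript, with its GC content, or with both was subtracted from each array. Where a gene was not well above background in one group on both arrays, only a bound on the fold is given. The bound was computed per channel after loess and Aquantile, from the lowest signal well above background, and it is open to dye bias.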

Results

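HCT116, a human colon cancer cell line, was transduced with lentivirus carrying either a vector for overexpression of FLANC, a long non-coding RNA, or the empty vector, and total RNA of both was compared on 2 arrays, 1 per replicate. Across the 4 channels, 51.4% to 55.5% of the spots were well above background and 0 were saturated. Among the negative control spots, 1.96% were above background in each channel. The arrays carried 0 probes named FLANC, and no sequence of it was used here, so its level could not be checked. Adjusted p-values rest only on the spread between these arrays, which the labels call biological replicates, and that spread was mostly pooled over genes. A gene whose own arrays lay far apart could therefore be called, such as RPLP0 (SD 0.81). The comparison asks which transcripts differ in HCT116 cells when FLANC is overexpressed. All log2 ratios below are FLANC vector over empty vector in the likely orientation, with replicate 2 as a dye swap.

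Replication-dependent histone genes and small structured RNAs were the named transcripts with the highest ratios, while 11 of 14 genes of fatty acid synthesis fell and 0 rose. RNVU1-18, a U1-type spliceosomal RNA, rose by a log2 ratio of 3.26 ± 0.59 (SD, n = 2, 9.58-fold), and SNORD3B-1, a U3 small nucleolar RNA that acts in ribosomal RNA processing, by 2.98 ± 0.067. The histone H3 gene H3C4 (7.02-fold) rose by 2.81 ± 0.20 and RN7SK, the RNA that holds the elongation factor P-TEFb inactive, by 2.47 ± 0.023. GNAS, which encodes the stimulatory G protein alpha subunit, fell with a log2 ratio of -1.60 ± 0.11, and SMC3, a core subunit of cohesin, with -1.53 ± 0.066. In all, 4111 of 13845 genes were called by limma (adjusted p under 0.05), 1362 higher and 2749 lower, and 5760 had an unadjusted p under 0.05.

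The 2 arrays had a Pearson correlation of 0.798 (Spearman 0.768) across genes after orientation, where genes are not independent replicates. At least 2-fold changes in the same direction on both arrays were found for 200 genes, 152 higher and 48 lower, against 0 genes at least 2-fold in opposite directions. Of the 152 higher, 30 were histone cluster genes, 16 small structured RNAs and 53 other protein-coding genes. A further 45 had no gene in the reference table and 8 were of other kinds. With replicate 2 turned the other way, so that FLANC RNA is Cy5 on both arrays, the correlation was -0.798, limma called 0 genes, and 12 had an unadjusted p under 0.05. Replicates of 1 comparison would not run against each other like this, so the values argue against the turned orientation. The 1362 to 2749 split also moved with the processing. It was 2618 higher and 3062 lower with Agilent's processed signals, 2894 and 3553 without background correction, and 26 and 7409 with median centring in place of loess. With loess followed by scaling between the arrays limma called 0 genes. Under median centring the median of all genes tested lay at -0.93 instead of -0.070, and directions hold only relative to that shift.

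**Figure D1:**
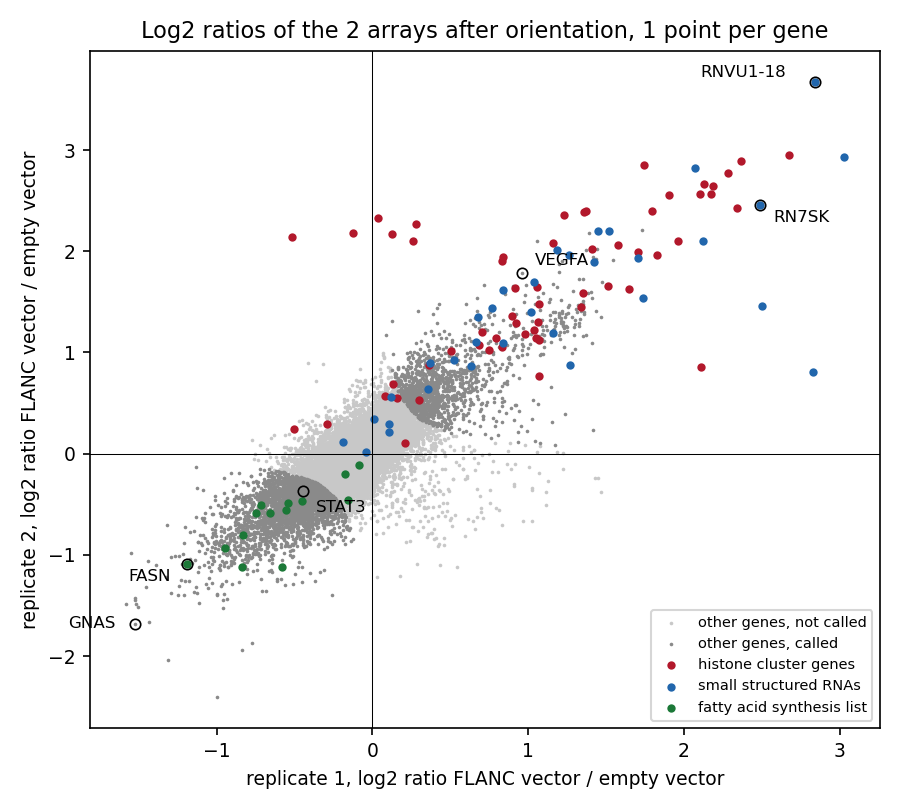
Log2 ratio of FLANC vector over empty vector on the array of replicate 1 (x axis) and of replicate 2 (y axis), 1 point per gene for 13845 genes. Histone cluster genes (red) and small structured RNAs (blue) reach the highest mean ratios among named genes, up to 3.26 for RNVU1-18, and members of the fatty acid synthesis list (green) lie below 0 on both arrays.

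Of the 12 named genes with the largest rise, 8 were histone genes and 4 were small RNAs. Beside those above they were H3C7 (2.63 ± 0.37), H2AC4 (2.53 ± 0.34), SNORA28 (2.45 ± 0.54), H3C10 (2.42 ± 0.32), H3C2 (2.40 ± 0.38), H4C5 (2.38 ± 0.059), H3C8 (2.37 ± 0.28) and H3C15 (2.34 ± 0.33). All 12 had adjusted p-values at or below 6.34e-05 in limma. The H3C4 probe lies on chromosome 6 at 26305237 to 26305296 (hg18), that of RNVU1-18 on chromosome 1 at 147490682 to 147490741, that of SNORD3B-1 on chromosome 17 at 18908088 to 18908147 and that of RN7SK on chromosome 6 at 52968618 to 52968677. These are members of multigene families with near-identical copies, so a probe can read several of them and the assignment to 1 gene is uncertain. In the fixed list of histone genes, 17 of 21 members rose and 1 fell, with 18 higher and 1 lower adjusted over the list alone. With median centring 4 were called higher and 3 lower, with a mean of 0.29 where the median of all genes was -0.93. The list mean was 1.29, with camera's adjusted p = 2.4e-15 at the preset correlation and adjusted p = 0.932 with an estimated correlation. The latter, at 1 residual degree of freedom, could hardly have passed for any list. H2AC6, a histone H2A gene, rose by 2.29 ± 0.78 at 1 probe and gave 1.65 ± 0.63 and 0.090 ± 0.059 at its other probes. The median start of the list's probes was 327 nt into the transcript, against 1933 nt over all genes tested, and with the position trend removed, a setting chosen after seeing the data, the list had 17 higher and 1 lower members and a mean of 1.13.

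VEGFA, the vascular endothelial growth factor gene, rose by a log2 ratio of 1.37 ± 0.58 (2.59-fold, limma adjusted p = 0.000722) at the probe on chromosome 6 from 43854201 to 43854612. Its other probe, from 43861489 to 43861548 and nearer the transcript's end, gave -0.23 ± 0.26, so the probes disagreed in sign. STAT3, a transcription factor of cytokine signalling, fell with -0.41 ± 0.053 (adjusted p = 0.0213) at a probe of 10 spots on chromosome 17 from 37719449 to 37719508, and its other probe, upstream in the transcript, gave -0.080 ± 0.019. With the position trend removed VEGFA stood at 1.39 and STAT3 at -0.19 (adjusted p = 0.191), which ended the STAT3 call. The median over its probes (-0.24, adjusted p = 0.12) and the GC trend removed (-0.27, adjusted p = 0.0586) also ended it, and median centring ended that of VEGFA (0.39, adjusted p = 0.41). In the list of STAT3 pathway members and targets, 3 of 28 rose and 10 fell, the same counts adjusted over the list alone. CEBPD, a C/EBP transcription factor, rose by 1.32 ± 0.26, while PIAS3, an inhibitor of STAT3, fell with -0.73 ± 0.12 and BCL3 with -0.67 ± 0.074. The list as a whole did not pass (mean -0.070, adjusted p = 0.791, and adjusted p = 0.932 with an estimated correlation). Of 20 angiogenic factors, VEGFA and EDN1 (0.39 ± 0.29) rose and VEGFB (-0.76 ± 0.038) and EFNB2 (-0.50 ± 0.15) fell, with only VEGFA higher and both falls kept adjusted over the list alone, and the list did not pass (adjusted p = 0.528).

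Genes of fatty acid synthesis fell together. Of 14 members tested, 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a list mean of -0.63 and camera's adjusted p = 1.97e-05, against adjusted p = 0.932 with an estimated correlation. FASN, the fatty acid synthase (chromosome 17, 77629505 to 77629564), fell with -1.14 ± 0.072, SCD, the stearoyl-CoA desaturase, with -0.98 ± 0.20, ELOVL6, a fatty acid elongase, with -0.94 ± 0.012 and ACSL3, an acyl-CoA synthetase, with -0.85 ± 0.38. All 14 members had the same sign on both arrays, against 78.4% of all genes tested. Every called gene had the same sign, and 11 members were called, so this share is largely set by the calls. The probes of this list started at a median of 3290.5 nt, and with the position trend removed 11 members were called lower, with a mean of -0.43 and adjusted p = 0.000113. In cholesterol biosynthesis 9 of 24 genes fell, such as DHCR7 (-0.78 ± 0.030), LSS (-0.48 ± 0.028) and CYP51A1 (-0.48 ± 0.036), and 2 rose, among them MVD (0.60 ± 0.42), and the list did not pass (adjusted p = 0.517).

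Among the largest falls were LMNB1, which encodes lamin B1 (-1.51 ± 0.0070), API5, an apoptosis inhibitor (-1.50 ± 0.024), PRKDC, the catalytic subunit of DNA-dependent protein kinase (-1.48 ± 0.057), and TMEM131 (-1.55 ± 0.16). GNG13 (-1.39 ± 0.78), FAM3C (-1.38 ± 0.097), PDS5A, a cohesin regulator (-1.34 ± 0.054), and CARM1, an arginine methyltransferase (-1.32 ± 0.11), followed. JAKMIP3 was not well above background with the FLANC vector on either array and was at least 2.59-fold lower (adjusted p = 0.00169). Other probes read smaller changes for API5 (-0.32 ± 0.21) and PDS5A (-0.22 and -0.61). The median over probes ended the calls of XPO5 (-0.30) and CASP2 (-0.30), and robust eBayes those of GNG13 (adjusted p = 0.0742) and JAKMIP3 (adjusted p = 0.118). Both probes of GNAS read alike, at -1.60 and -1.59. The GNAS probe lies on chromosome 20 at 56919399 to 56919458 (hg18) and the SMC3 probe on chromosome 10 at 112352641 to 112352700.

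In the G2/M and mitosis list 16 of 44 genes fell and 2 rose, the same adjusted over the list alone. KIF11, a mitotic kinesin, fell with -1.24 ± 0.013, TOP2A, topoisomerase II alpha, with -0.95 ± 0.019, BUB1B, a spindle checkpoint kinase, with -0.86 ± 0.32 and ASPM with -0.84 ± 0.10. In the G1/S and DNA replication list 9 of 44 fell and 1 rose, also unchanged adjusted over the list alone, with SLBP, the histone mRNA stem-loop binding protein, at -1.15 ± 0.051, RFC3 at -1.03 ± 0.14, RRM2 at -0.82 ± 0.13 and MCM2 at -0.74 ± 0.21. Over all 13845 genes tested 2749 were called lower and 1362 higher, a share of falls close to that of the G1/S list. Of 28 RNA and chromatin regulators 11 fell and 0 rose (12 adjusted over the list alone), led by the exonuclease XRN2 (-0.83 ± 0.34), XPO5 (-0.75 ± 0.20), HNRNPU (-0.66 ± 0.16) and STAU1 (-0.66 ± 0.033). None of these 3 lists passed as a whole, with adjusted p = 0.142 for G2/M and mitosis, 0.791 for G1/S and DNA replication and 0.142 for the regulators. Without the filter on dim probes G2/M and mitosis (adjusted p = 0.00303) and the regulators (adjusted p = 0.00319) passed as lower, and all 3 passed with median centring (adjusted p at or below 0.0143). All 3 had an adjusted p = 0.932 with an estimated correlation. With the position trend removed the regulators had 5 members higher and 8 lower, G2/M and mitosis 3 higher and 13 lower, and G1/S and DNA replication 5 higher and 5 lower.

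**Figure D2:**
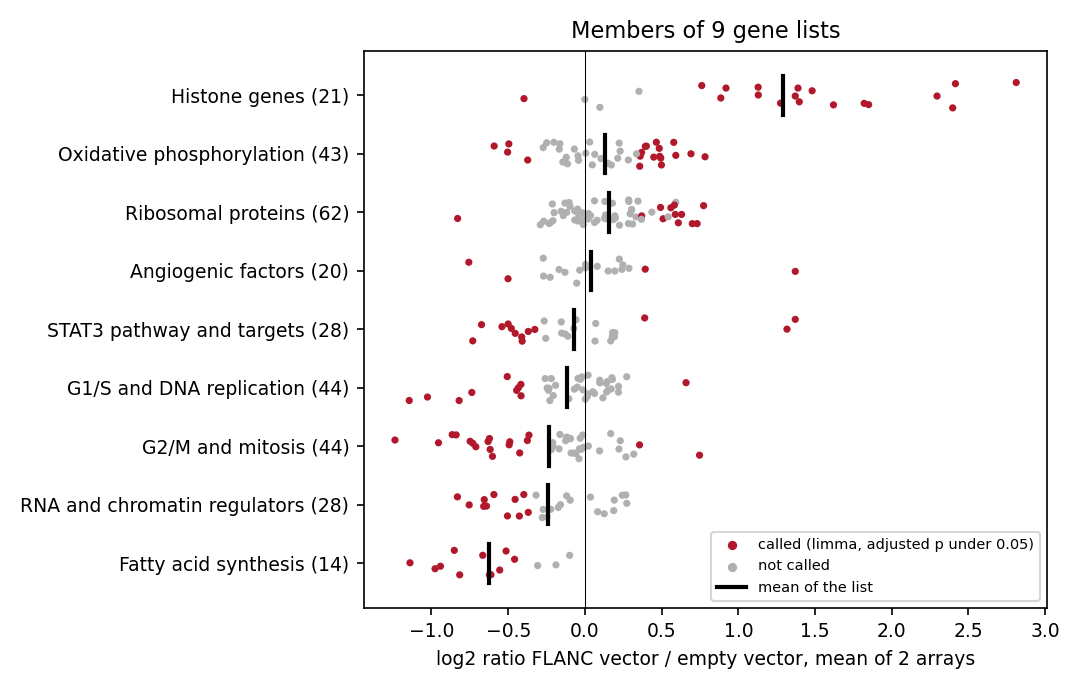
Log2 ratio of FLANC vector over empty vector, mean of the 2 arrays (x axis), for each tested member of 9 gene lists, with the number of members in brackets. Red points were called by limma, grey points were not, and black bars are list means, which run from 1.29 for histone genes to -0.63 for fatty acid synthesis.

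Oxidative phosphorylation and ribosomal protein genes passed camera as higher, with small means, against adjusted p = 0.932 with an estimated correlation for both. In oxidative phosphorylation 15 of 43 genes rose and 4 fell (16 and 4 adjusted over the list alone), among them UQCRH (0.78 ± 0.35), COX7A2 (0.69 ± 0.20) and COX5B (0.59 ± 0.15) as higher and ATP5F1A (-0.59 ± 0.050), an ATP synthase subunit, as lower. The list mean was 0.13 (adjusted p = 0.0109). Its probes started at a median of 564 nt, and with the position trend removed the mean was 0.039 with 9 members higher and 6 lower (adjusted p = 0.991). Of 62 ribosomal protein genes 11 rose, such as RPS12 (0.77 ± 0.10), RPL31 (0.73 ± 0.60) and RPS24 (0.70 ± 0.31), and RPLP0 fell (-0.83 ± 0.81), with 6 higher and 1 lower adjusted over the list alone. The ribosomal list mean of 0.15 (camera's adjusted p = 0.00664) joined 0.61 on replicate 1 and -0.30 on replicate 2. Only 18 of 62 members had the same sign on both arrays, against 78.4% of all genes tested. Means of opposite sign after orientation are what a dye effect would give, so the call of this list is not read as a rise in expression. With the position trend removed the ribosomal mean was 0.021 (adjusted p = 0.991), and it was -0.0077 with Agilent's processed signals. With replicate 2 turned the other way it was 0.46 (adjusted p = 2.12e-115). Under median centring the means of these lists were -0.94 and -0.82.

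The other lists fixed beforehand did not pass, and counts adjusted over the list alone differed from those below by at most 2 members. Since 2749 of all 13845 genes tested were called lower and 1362 higher, more falls than rises in a list do not by themselves set it apart. Of p53 targets 5 of 32 rose and 8 fell, with BAX, a pro-apoptotic BCL2 family member, at 1.04 ± 0.62 and CCNG1 at -1.03 ± 0.071. Among pro-apoptotic genes 4 of 28 rose and 5 fell, with DIABLO at 1.41 ± 0.089 (0.12 at its other probe) and CASP2 at -0.86 ± 0.10 (0.26 at its other probe). Of anti-apoptotic genes 2 of 16 rose and 3 fell, BIRC2 at -0.60 ± 0.021. Of interferon-stimulated genes 3 of 27 rose and 4 fell, with STAT2 at 0.57 ± 0.23 and IFI35 at 0.55 ± 0.32 against IRF7 at -0.49 ± 0.10. In antigen presentation 3 of 15 rose, such as PSMB10 (0.54 ± 0.054), and 3 fell, such as HLA-C (-0.51 ± 0.11). In the NF-kB list 1 of 13 rose and 1 fell. Wnt/beta-catenin targets had 1 of 20 higher and 6 lower, led by DKK1 (-0.70 ± 0.11), RNF43 (-0.65 ± 0.14) and MYC (-0.54 ± 0.23), and immediate early and MAPK feedback genes 2 of 33 higher and 7 lower, led by SPRED2 (-0.88 ± 0.037) and EREG (-0.70 ± 0.0012). Of MYC targets and ribosome biogenesis genes 5 of 36 rose and 6 fell. Mesenchymal and EMT genes had 4 of 19 lower and 0 higher, among them AXL (-0.71 ± 0.12) and LOXL2 (-0.67 ± 0.035), and epithelial genes 6 of 28 lower and 1 higher, among them TJP1 (-0.55 ± 0.14) and CDH1 (-0.55 ± 0.080). TGF-beta targets had 1 of 14 higher and 3 lower, the Notch pathway 1 of 12 higher (MAML1 at 1.23 ± 0.029, with -0.26 at its other probe) and 2 lower, with NOTCH3 at -0.83 ± 0.16. In hypoxia and glycolysis 2 of 30 rose, led by PFKL (1.23 ± 0.0046), and 6 fell, led by PGK1 (-0.66 ± 0.0040). Metallothioneins and NRF2 targets had 7 of 30 higher and 3 lower, the unfolded protein response and ATF4 targets 4 of 39 higher and 4 lower, and heat shock proteins 0 of 22 higher and 3 lower. Long non-coding RNAs had 4 of 19 higher and 2 lower, with MIR17HG at 1.41 ± 0.33, ZFAS1 at 0.61 ± 0.021 and UCA1 at -0.65 ± 0.13. Enterocyte and goblet genes had 2 of 7 lower and 0 higher, cancer-testis antigens 1 of 5 higher and 2 lower, and housekeeping genes 2 of 20 higher and 6 lower, with POLR2A at -0.85 ± 0.023 and TFRC at -0.75 ± 0.10. With median centring housekeeping, epithelial and cholesterol biosynthesis genes passed as lower (adjusted p = 0.0143, 0.0481 and 0.0483), against adjusted p = 0.932 with an estimated correlation. Means and camera's direction differed in sign for interferon-stimulated genes, antigen presentation, the NF-kB list and the unfolded protein response list, each with a mean between -0.040 and -0.016. Means and medians differed in sign for metallothioneins and NRF2 targets (0.044 and -0.067), for the unfolded protein response list (-0.016 and 0.051) and for kidney packaging cell markers (0.20 and -0.098).

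Markers of other cell types were mostly at the background. Of 14 fibroblast markers 2 were tested, COL1A1 at -0.14 ± 0.21 and DPT at -0.029 ± 0.13, and neither passed. Of 6 blood cell markers tested 1 rose, CD79A (0.57 ± 0.016), and of 5 markers of kidney-derived packaging cells tested 2 rose, HOXA10 (1.14 ± 0.066, with -0.071 at its other probe) and EN2 (0.89 ± 0.00083), and PAX2 fell (-0.66 ± 0.0084).

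The ratio changed with the start position of the probe, compared across probes of many transcripts. Transcript lengths were not assigned, so this trend, and the settings that remove it, could not be told apart from a trend with transcript length. Within 1 transcript the probe nearer the start read higher by a median of 0.164 over 2174 pairs. Across 16530 probes, Spearman's rho between start position and log2 ratio was -0.449, at -0.394 on replicate 1 and -0.445 on replicate 2. The median log2 ratio was 0.22 for 544 probes starting within the first 250 nt and -0.29 for 1606 probes starting beyond 5000 nt. With the position trend removed, 1929 genes were called higher and 1914 lower, and 2891 of the 4111 called genes were among them. Among named genes the calls of EFNB2 (adjusted p = 0.0571), LSS (0.0697) and TJP1 (0.0959) ended with it, beside STAT3. At least 2-fold changes the same way on both arrays then numbered 158, with 141 higher and 17 lower.

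**Figure D3:**
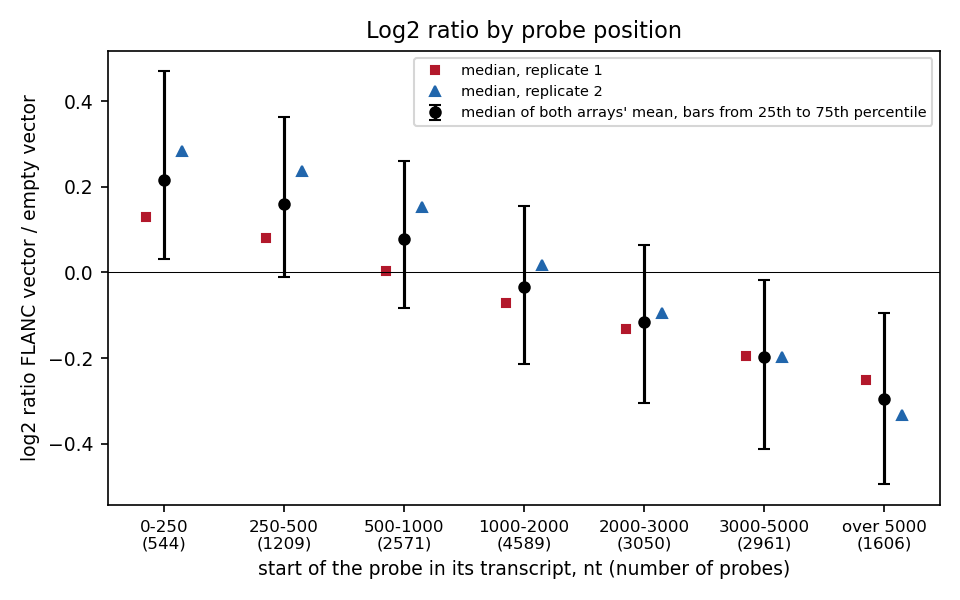
Log2 ratio of FLANC vector over empty vector (y axis) by the start of the probe in its transcript in nt (x axis, number of probes in brackets). Black points are medians of the mean of both arrays with bars from the 25th to the 75th percentile, red squares and blue triangles are the medians of replicate 1 and of replicate 2, and the black medians fall from 0.22 to -0.29.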

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

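The calls depended on the orientation of replicate 2, although the negative correlation below argues against turning it. With it turned the other way, 0 genes were called, 0 changed at least 2-fold the same way on both arrays, the correlation of the arrays was -0.798 and 2 lists were called, ribosomal proteins (mean 0.46, adjusted p = 2.12e-115) and housekeeping genes (adjusted p = 4.91e-05). The mean changed sign for 12 of 33 lists, which among lists called under any setting and those of STAT3 and angiogenic factors were Angiogenic factors (-0.082), Fatty acid synthesis (0.019), Histone genes (-0.23) and Housekeeping genes (0.12). Among single genes the mean log2 ratio changed sign for RNVU1-18 (-0.42), H3C4 (-0.14), H3C7 (-0.26), H2AC4 (-0.24), SNORA28 (-0.38), H3C10 (-0.23), H3C2 (-0.27), H4C5 (-0.042), H3C8 (-0.20), H3C15 (-0.23), VEGFA (-0.41), CARM1 (0.076), PDS5A (0.038) and GNG13 (0.55). It also did for LMNB1 (0.0049), TMEM131 (0.12), GNAS (0.076), JAKMIP3 (0.70), CEBPD (-0.18), EDN1 (-0.20), H2AC6 (-0.55), SCD (0.14), ACSL3 (0.27), ATP5F1A (0.036), RPLP0 (0.57), KIF11 (0.0091), ASPM (0.071) and RFC3 (0.096). The same held for RRM2 (0.089), STAU1 (0.023), DHCR7 (0.021), LSS (0.020), MVD (-0.30), DKK1 (0.075), SPRED2 (0.026), DIABLO (-0.063), CASP2 (0.073), BAX (-0.44), LOXL2 (0.025), TJP1 (0.10), NOTCH3 (0.11) and PFKL (-0.0032). So it did for PGK1 (0.0028), MIR17HG (-0.23), ZFAS1 (-0.015), STAT2 (-0.16), IFI35 (-0.23), HLA-C (0.080), CD79A (-0.012), HOXA10 (-0.047), PAX2 (0.0059), COL1A1 (0.15), DPT (0.090), POLR2A (0.017) and TFRC (0.071). Of 94 called genes that the text names, 53 changed sign and 41 were no longer past the threshold, the direct consequence of turning 1 of 2 arrays.

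Median centring in place of loess gave 7435 called genes, 2219 changed at least 2-fold and 8 called lists, with the median of all genes at -0.93. The mean of 11 of 33 lists changed sign, among the same lists Angiogenic factors (-0.75), Oxidative phosphorylation (-0.94) and Ribosomal proteins (-0.82). The sign also changed for UQCRH (-0.23), COX7A2 (-0.31), COX5B (-0.49), RPS12 (-0.25), RPL31 (-0.25), RPS24 (-0.30), MVD (-0.22), BAX (-0.12), ZFAS1 (-0.46), STAT2 (-0.59), IFI35 (-0.048), PSMB10 (-0.49), CD79A (-0.44), HOXA10 (-0.017), EN2 (-0.24) and DPT (0.056), of which 15 kept their direction relative to the median of all genes. Of the 6 lists gained by median centring, G2/M and mitosis had an adjusted p of 2.83e-05, the RNA and chromatin regulators 0.000985, G1/S and DNA replication 0.0143, housekeeping genes 0.0143, epithelial genes 0.0481 and cholesterol biosynthesis 0.0483. Loess followed by scaling between the arrays called 0 genes (2184 with an unadjusted p under 0.05), left 49 with a change of at least 2-fold, and changed the sign for angiogenic factors (-0.0023) and DPT (0.018). The cause was not tested.

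Without background correction 6447 genes were called, 303 changed at least 2-fold, 2 lists were called and DPT stood at 0.066. With Agilent's processed signals and with the authors' log ratios alike, 563 genes changed at least 2-fold, 2 lists were called, the ribosomal mean was -0.0077 and DPT 0.016. Processed signals with loess gave 566 and 2. Limma's treat left 1061 called genes. Camera with an estimated correlation and fry each called 0 lists. The cause was not tested.

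The 3 settings with trends removed were chosen after seeing the data. With the position trend removed 2 lists were called, and the sign changed for 9 of 33 list means, among them the STAT3 list (0.030), and for COL1A1 (0.13) and DPT (0.016). With position and GC trends removed 110 genes changed at least 2-fold, 2 lists were called, the mean of 10 lists changed sign, and the STAT3 list stood at 0.015 and COL1A1 at 0.13. The cause was not tested.

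Without replicate 1 or without replicate 2, at least 2-fold changes numbered 285 to 420. The ribosomal mean ran from -0.30 to 0.61, angiogenic factors from -0.043 to 0.12, COL1A1 from -0.29 to 0.0069 and DPT from -0.12 to 0.061. Calls and the correlation between arrays have no value when 1 array is left out. No paired analysis was possible because each array already sets the RNAs of 1 replicate against each other, so the pairing is part of the ratio and no further block could be fitted.

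The histone mean kept its sign under each setting but the turned orientation, as did fatty acid synthesis. Of the 94 named calls, all kept call and side with Aquantile, the eBayes trend, outlier spots kept and the processed signals, 93 with an offset of 0 and with the GC trend removed, 91 without the filter and with robust eBayes, 90 with the median over probes and with the position trend removed, and 71 with treat. With loess followed by scaling all 94 lost the call but 0 changed sign, with VEGFA at 1.35 and STAT3 at -0.49. With median centring 72 kept call and side, 15 changed sign and 7 lost the call (adjusted p), VEGFA (0.41), CEBPD (0.77), EDN1 (0.755), DIABLO (0.45), MAML1 (0.708), PFKL (0.86) and MIR17HG (0.0888). Genes not well above background in 1 group on both arrays, 325 with the FLANC vector and 23 with the empty vector, have ratios pulled towards 0, so signal over background limits the size of those falls and rises.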

Other observations

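Some tests were chosen only after the result was seen: those of dye bias and S phase for the histone genes and small RNAs, those of GC content and RNA integrity for the probe pairs, and that of dye bias for fatty acid synthesis. The tests of the position trend, and of GC content for fatty acid synthesis, rest on settings that were also chosen after seeing the data.

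Small structured RNAs as a class, which here also counts the longer 28S and 18S ribosomal RNAs, were higher with the FLANC vector. Of 33 tested, 27 were called higher and 0 lower in limma, against 1335 higher of the 13812 other genes (Fisher's exact p = 3.13e-22), with a median log2 ratio of 1.21. With median centring 8 were called higher and 1 lower, with a median of 0.54 where that of all genes was -0.93. The class was grouped after values were seen, and it spans RNAs of different origin. Members are RNU2-2, a U2 spliceosomal RNA (2.11 ± 0.11, SE, n = 2), RPPH1, the RNA of RNase P (1.86 ± 0.16), RMRP, the RNA of RNase MRP (1.82 ± 0.17), TERC, the telomerase RNA (1.60 ± 0.17), and RN7SL1, the RNA of the signal recognition particle (0.97 ± 0.12). The 28S ribosomal RNA RNA28SN5 stood at 1.98 ± 0.20 and the 18S RNA RNA18SN5 at 0.88 ± 0.13, and both are among the 27 called higher. These RNAs share sequence with pseudogenes and sister copies, so cross-hybridisation leaves the exact gene uncertain.

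Histone genes separated by class. Of 19 replication-dependent genes 17 were called higher and 0 lower, with a median of 1.39. Of 10 replication-independent genes, whose mRNAs carry a poly(A) tail, H3-3A rose (0.54 ± 0.12 SE) and MACROH2A2 fell (-0.51 ± 0.11), and the median was -0.0127. Within H2AC6 the probes starting at 30 nt and 88 nt read 1.65 and 2.29, and the probe starting at 1100 nt read 0.090.

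Histone genes and small RNAs rose together, and 3 technical and 1 biological explanation were weighed. Dye bias is excluded as the whole cause, given that replicate 2 was a dye swap. After orientation 94.2% of 52 members had the same sign on both arrays, against 78.4% of all genes tested. Every called gene had the same sign, so this share is partly set by the calls. The mean of the histone list was 1.06 on replicate 1 and 1.51 on replicate 2. The position trend is excluded as the whole cause, since the histone mean was 1.13 with the trend removed. A larger share of cells in S phase is excluded as the whole cause, since the G1/S list did not rise. The list mean was -0.117 ± 0.0526 (SE over its 44 member genes, not over arrays), at -0.169 on replicate 1 and -0.0648 on replicate 2. With the position trend removed the mean was -0.011. More RNA without a poly(A) tail in the labelled FLANC material may account for it, with a median of -0.0127 for replication-independent histone genes against 1.39 for the others, but a change of these RNAs in the cells was not separated from it.

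Within 1 transcript, the probe nearer the start read higher with the FLANC vector, by a median of 0.164 (95% interval 0.143 to 0.191) over 2174 pairs. The interval comes from resampling pairs and leaves out the spread between arrays. The medians of the arrays, 0.114 on replicate 1 and 0.231 on replicate 2, both lie outside it. Dye bias is excluded only as the whole cause, since both medians were above 0, given that replicate 2 was a dye swap. GC content is excluded only as the whole cause, since 619 pairs matched for it still differed by 0.114, less than all pairs did. Changed ends in a subset of genes are likewise excluded only as the whole cause, by 78.1% of 1099 distant pairs in the same direction. Such changes on top of the general shift were not tested. The difference grew with the distance between the probes (Spearman's rho 0.344), from 0.012 within 500 nt to 0.351 beyond 2000 nt, which is in line with unequal RNA integrity or cDNA priming between the preparations and might also bear on the rise of RNA without a poly(A) tail. No RNA integrity values are given in the sources used here.

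Fatty acid synthesis genes fell, and the position trend (mean of -0.433 with the trend removed, camera's adjusted p = 0.000113) and GC content (mean of -0.517, adjusted p = 2.92e-05) were each excluded as the whole cause. The test of dye bias (100% of 14 members with the same sign on both arrays) could hardly fail. All 4111 called genes had the same sign, and 11 members were called. The list mean was -0.606 on replicate 1 and -0.644 on replicate 2, which argues against a dye effect if replicate 2 was a dye swap. The list had an adjusted p = 0.932 with an estimated correlation and 0.308 with fry. With 1 residual degree of freedom the first of these could hardly pass, so it does not bear on the fall. Differences between the cultures, such as cell density, were not tested, and the cause of the fall is left open.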
